A study of Mus musculus with 2 samples.

How the data were processed

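Single-cell transcriptomes of lung fibroblastic stroma from C57Bl/6J mice were compared between 1 library from animals on a high fat diet (HFD) and 1 library from animals on normal chow (NC), each after 16 weeks of feeding. Per the labels' protocols, a 10x Genomics single-cell kit was used and the cells were analysed by a commercial provider. Per the submitters' processing notes, STAR and the mm39 build were used, with versions and molecule counting not given in the sources used here. With 1 library per group there was no replicate check and no test. Every interval covers counting error only.

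The deposited tables hold log2 values of CPM (counts scaled to the same total in every cell) plus a pseudocount of 1 per cell for 21014 genes, as found from the values, since the headers name no unit. The deposited tables also give a total per cell, an estimated count that was not whole in 7.24% of HFD and 5.59% of NC cells, and, per the file headers, mitochondrial and ribosomal shares in percent. A column of cell numbers in the tables lists 9573 HFD and 11241 NC cells, against 6971 and 9015 cells with values. Counts were recovered by undoing the log2 scale and multiplying by each cell's total. Within a tolerance of 0.01, 98.8% of nonzero HFD values and 98.96% of NC values came out whole, and all were rounded. A gene name table gave a symbol for 20180 identifiers (96.03%), and 36 that share a symbol kept their identifier. The reference annotation used here belongs to an older build, so it gave names and transcript lengths but no coordinates.

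The recovered counts did not behave like single molecules. Among genes seen in 0.1 to 1% of kept cells, the mean count of a positive cell had a median over genes of 3.25 in HFD and 2.66 in NC. Intervals were therefore computed on effective counts, the count divided by a variance factor of 4.85 in HFD and 3.98 in NC. Minimums that had been set in molecules were applied to effective counts. Near-identical copies can share reads, so values of Mir682, Mir6236, Hsp25-ps1, Hspb1, H2-Q7 and mitochondrially encoded genes are uncertain.

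Cells with at least 500 detected genes and at most 10% mitochondrial counts were kept. This left out 12.7% of HFD and 9.71% of NC cells. Scrublet (in scanpy 1.11.5, expected rate 6%) marked 0 of the kept cells in either library, so no cell was removed as a doublet. Whether the caller missed doublets or they had been left out before deposit is not known. Cell classes were taken from the deposited annotation, which names Asc1, Gas6 and Pi16 fibroblasts, myofibroblasts and pericytes, with a finer column that splits an SNAT2 subset from the Asc1 class. The design had foreseen clusters found here as the main classes, and these became an alternative. They used 2000 variable genes, 30 principal components, 15 neighbours and Leiden (leidenalg 0.10.2) at resolutions 0.4, 0.8 and 1.5, or at 0.8 with genes centred per library. Clusters were named from fixed markers. A minimum score of 0.2 and, for names other than fibroblasts, a marker among the 10 leading genes were required only after the clusters had been seen. These left 0.706% of HFD and 1.38% of NC cells unnamed at resolution 0.8.

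The fibroblast comparison pools the Asc1, Gas6, Pi16 and myofibroblast classes. Counts were summed per library and class and given as CPM, with exact conditional 95% Poisson intervals of the HFD over NC ratio. Shares have exact Clopper-Pearson intervals. The design, the marker and gene lists and the rule for named genes were fixed before the data were examined. Named genes had at least 100 effective counts and 50 CPM in at least 1 library. They were the 12 highest and 12 lowest ratios, ranked by the interval bound nearest to 1, and 5 of each in single classes. Mitochondrially encoded, ribosomal protein, predicted, haemoglobin and immunoglobulin genes were not ranked. A gene that met the rule in a single class is not reported here. Up to 4 members per list, those with the bound farthest from 1, were named, and all sex-linked transcripts measured. Of 30 gene lists, members with at least 50 effective counts over both libraries were used, and a ratio of at least 1.5 in either direction was called higher or lower by size, with no test. The list genes Plin5, Cfd, Pla2g2d, Stra6 and Cdkn2a were not analysed here. Each list median was placed among 10000 random lists of its size matched on expression, as a description of these libraries.

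Data were simulated for 2576 genes of the fibroblast comparison, 200 of them changed. Of the intervals, 94.6% held the simulated ratio, against 64.01% without the variance factor. The simulation used that same factor and no differences among cells, so it checked the calculation and not the spread of the real data. Of 100 unchanged lists, 4% lay outside the central 95% of random lists. Alternatives covered cell filters, doublets, clusterings, classes left out or weighted equally, scaling by TMM, median of ratios or other totals, means per cell, thinning to 2000 counts per cell and count minimums. Both scalings were written in numpy 2.4.6, without the packages they are named for. Python 3.11.15, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.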

Results

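Lung fibroblastic stromal cells of C57Bl/6J mice were profiled by droplet-based single-cell RNA sequencing after 16 weeks of high fat diet (HFD, 1 library) or normal chow (NC, 1 library). The kept cells held about 71014900 counts in 6089 HFD cells and about 69940500 counts in 8140 NC cells. Median depth was 10045 counts and 1429 genes per HFD cell, and 7524 counts and 1355 genes per NC cell, a ratio of 1.34 in counts. The median mitochondrial share was 3.79% in HFD and 3.57% in NC. Pecam1, Epcam and Ptprc, markers of endothelial, epithelial and immune cells, had a count in 0 of 6971 HFD and 0 of 9015 NC cells. The same held for Msln and Sftpc. Whether cells with these genes were left out before deposit is not known, so the zeros are no measure of purity. Other genes of such cells had a count in a few cells of HFD and NC, 131 and 112 for the immune gene Lyz2, 28 and 14 for the epithelial gene Krt18 and 11 and 21 for the endothelial gene Kdr. Summed over fixed markers, levels in the kept cells of HFD and NC were 26.5 and 41.8 CPM for monocytes and interstitial macrophages. That sum was lower in HFD through Plac8, at 15.8 and 35.2 CPM, while Lyz2, at 8.52 and 4.16 CPM, was higher. Over all deposited cells, 1 HFD cell held 256 of 637 Lyz2 counts (40.2%), against at most 11 of 320 in an NC cell. The higher Lyz2 level thus rests largely on 1 cell. Sums were 2.52 and 9.18 CPM for dendritic cells, 1.97 and 6.59 for neutrophils and 0.591 and 2.30 for T cells, lower in HFD. For natural killer and innate lymphoid cells they were 3.79 and 3.69 CPM. There were no replicates, so each difference is between these 2 libraries.

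The first comparison asked how the stromal classes of the deposited annotation were represented on each diet. The class labelled pericytes made up 9.79% of HFD cells (596 cells, interval 9.05 to 10.6%) and 3.07% of NC cells (250 cells, 2.71 to 3.47%), a ratio of 3.19. Gas6 fibroblasts made up 17.98% of HFD cells (17.03 to 18.97%) and 24.6% of NC cells (23.7 to 25.5%). Pi16 fibroblasts made up 13.1% (12.2 to 13.9%) and 15.01% (14.2 to 15.8%). Asc1 fibroblasts, the most numerous class in both libraries, made up 50.8% (49.5 to 52.04%) and 49.1% (48.04 to 50.2%), and myofibroblasts 8.38% (7.69 to 9.10%) and 8.19% (7.61 to 8.81%), with overlapping intervals in both. With a stricter cell filter (at least 1000 genes and at most 5% mitochondrial counts) these classes stood further apart. Asc1 fibroblasts were at 50.9% and 45.4%, and myofibroblasts at 6.27% and 4.69%. Kept myofibroblasts had medians of 1032.5 genes in HFD and 960 in NC, on either side of that limit, so depth can make such shifts. The class labelled pericytes then fell to 4.36% and 1.51%, a ratio of 2.89. Its median mitochondrial shares, 6.13% and 5.72%, lay above the stricter limit. In the main setting, the larger share of the class labelled pericytes in HFD lowers the shares of the other classes there. Of the 5493 HFD and 7890 NC cells in the pooled fibroblast classes, 3092 and 3999 were Asc1 fibroblasts, a wider gap than among all kept cells. Pi16 fibroblasts numbered 796 and 1222, a narrower gap. The class labelled pericytes carried the smooth muscle genes Acta2, at 12769 and 12126 CPM in HFD and NC, and Myh11, at 2878 and 2369 CPM. Of the pericyte genes, Cspg4, at 134 and 99.8 CPM, and Notch3, at 126 and 87.3 CPM, were above their levels in the pooled fibroblasts (3.51 and 5.51, and 3.69 and 3.69 CPM), while Higd1b, at 3.86 and 2.04 CPM, was below (7.08 and 2.69 CPM). In clusters found here at resolution 0.8, smooth muscle-like cells made up 9.46% of HFD and 2.97% of NC cells. The alveolar fibroblast-like share in those clusters was 61.2% in HFD and 57.4% in NC, the opposite order to the 68.8% and 73.7% of the Asc1 and Gas6 classes together. This rested on the name of a single cluster (317 HFD and 970 NC cells, 79.4% of them in the Gas6 class). Its marker score was 0.423 as adventitial and 0.350 as alveolar. Its leading genes included Mt1, Mt2, Thbs1 and Il6 and no marker of either name. Counted as alveolar, it gave 66.4% and 69.3%, the order of the annotation and of the other clusterings as named here. Dissociation and gating can also affect shares, which was not tested. Slc7a10, which encodes the transporter Asc-1, itself differed within the Asc1 class (218 and 138 CPM in HFD and NC).

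**Figure D1:**
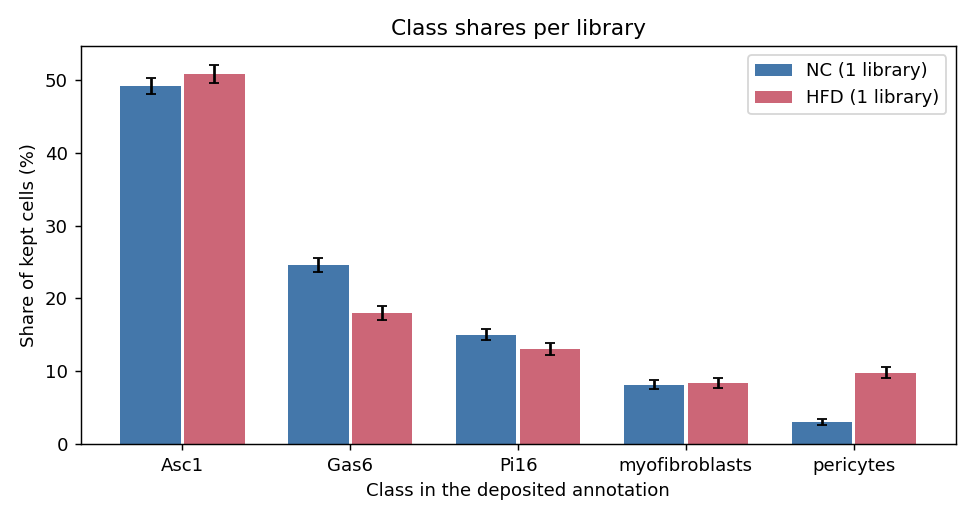
Share of kept cells (%) in each class of the deposited annotation for the HFD and NC libraries, with exact 95% binomial intervals as error bars, which cover counting error only. The class labelled pericytes stood at 9.79% in HFD and 3.07% in NC, and Gas6 fibroblasts at 17.98% and 24.6%.

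The second comparison asked which transcripts differed between the diets in the pooled fibroblasts. Transcripts of glucocorticoid-induced genes, endoplasmic reticulum chaperones, sterol synthesis enzymes and chemokines were lower in HFD, and Mfap4 and Hes1 were higher. Of 29 measured WNT, BMP and growth factor niche genes, 5 were higher by size and 2 lower. Most genes differed little, since over 2576 genes the median absolute log2 ratio was 0.16 and 94.4% lay within 1.5-fold. Mfap4, a microfibril-associated glycoprotein, was at 2492 against 1141 CPM (HFD over NC ratio 2.18, 2.14 to 2.22), and Hes1, an effector of Notch signalling, at 239.5 against 117 CPM (2.04, 1.93 to 2.16). The ratio was 1.98 (1.80 to 2.18) for Fabp3, a fatty acid-binding protein, 1.99 (1.80 to 2.21) for Gucy1a1, a subunit of soluble guanylate cyclase, and 1.83 (1.69 to 1.98) for Slc7a10, a neutral amino acid transporter. Lrat, which esterifies retinol, was at 170.1 against 98.6 CPM (1.72, 1.61 to 1.84). The ratios of the other genes named at this end were 2.44 for Mir682, 2.13 for Smim4, 2.12 for Fam189a2, 1.83 for Aqp1, 1.75 for Anapc13 and 1.70 for Cdkn2c. Of these 12 genes, 10 were higher in HFD in all 5 classes, Fam189a2 in 4 and Aqp1 in 3. With the fibroblast classes weighted equally, the log2 ratio of Aqp1 was −0.47. That of Mfap4 ran from 0.76 to 1.21 over the alternatives. Mfap4 and Slc7a10 are also fixed markers of alveolar fibroblasts, Gucy1a1 of pericytes and Has1, named below, of adventitial fibroblasts.

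At the low end, the glucocorticoid-induced gene Zbtb16 was at 15.2 against 63.5 CPM (ratio 0.240, 0.204 to 0.282), and the ratios of Tsc22d3, Errfi1 and Sgk1, other such genes, were 0.394 (0.373 to 0.417), 0.405 (0.387 to 0.424) and 0.418 (0.395 to 0.443). Hspa5, the main chaperone of the endoplasmic reticulum, was at 518 against 1376 CPM (0.376, 0.366 to 0.387), and Manf, a secreted factor induced by stress of that compartment, had a ratio of 0.384 (0.360 to 0.409). Has1, a hyaluronan synthase, was at 104 against 291 CPM (0.358, 0.336 to 0.382), and Mt2, a metallothionein, at 575 against 1309 CPM (0.439, 0.428 to 0.452). The ratios of the other genes named at this end were 0.378 for Ifi205, 0.401 for Mir6236, 0.444 for the chemokine Ccl7 and 0.443 for the heat shock gene Hsph1. All 12 were lower in HFD in each of the 5 classes. Genes at both ends were picked on the pooled fibroblast classes of the same libraries, so a shared direction among these classes is no separate support. Of the 24 genes named at both ends, 11 would be named without a minimum CPM and 15 without the Asc1 class.

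**Figure D2:**
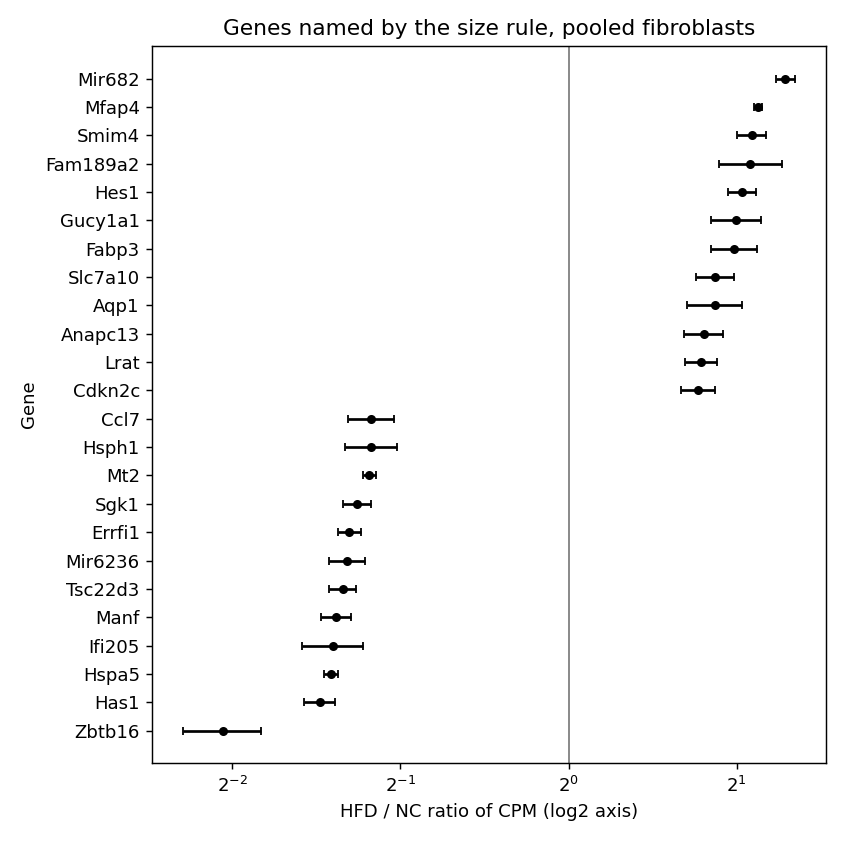
HFD over NC ratio of CPM (log2 axis) for the genes named by size in the pooled fibroblasts, with 95% counting intervals. Ratios ran from 0.240 for Zbtb16 to 2.44 for Mir682.

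Of the 30 gene lists, 16 had a median log2 ratio below the central 95% of random lists and 3 above it. The lists of glucocorticoid targets, unfolded protein response, stromal chemokines and NF-kB signalling were also below it in each of the 4 fibroblast classes, and the other 12 in 0 to 3 of them. The glucocorticoid targets were at −0.72, with 8 of 14 measured members lower by size and 0 higher. Their median was below 0 in each class, from −1.08 in Asc1 to −0.58 in Pi16 fibroblasts. The unfolded protein and integrated stress response was at −0.55 (8 of 19 lower, 0 higher), including Sdf2l1 at a ratio of 0.387 (0.322 to 0.464) and Creld2 at 0.424 (0.350 to 0.511). Cholesterol synthesis and SREBP2 targets were at −0.54 (12 of 25 lower, 0 higher), and the sterol synthesis enzymes Sqle, Cyp51 and Idi1 had ratios of 0.355 (0.250 to 0.495), 0.459 (0.388 to 0.541) and 0.497 (0.428 to 0.576). Fatty acid synthesis and SREBP1 targets were at −0.27, with 1 of 14 lower by size. Immediate early and dissociation stress genes, which respond to tissue handling, were low as well, at −0.17 (3 of 29 lower, 0 higher).

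Stromal chemokines and cytokines had a median log2 ratio of −0.52 (10 of 24 lower by size, 0 higher), with Il11 at a ratio of 0.270 (0.189 to 0.378) and Cxcl2 at 0.410 (0.354 to 0.474). Cxcl9 had 4 counts in HFD and 276 in NC. NF-kB feedback and inflammatory signalling was at −0.42 (5 of 21 lower), including Nfkb1 at 0.525 (0.492 to 0.560). The senescence-associated list was at −0.36 (6 of 17 lower), including Cdkn1a, also a glucocorticoid list member, at 0.609 (0.580 to 0.639). Smaller medians were −0.18 for complement and acute phase genes (C1qtnf2, a member, was higher at 1.59 (1.46 to 1.72)), −0.18 for MHC class I presentation, −0.12 for antioxidant and NRF2 targets and −0.15 for the insulin and IGF axis, with the growth factor Igf1 at 0.494 (0.450 to 0.541). Without the Asc1 class, the insulin and IGF median was 0.020.

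Matrix genes were slightly lower in HFD in the pooled fibroblasts, but not in each class. Collagens had a median log2 ratio of −0.21, with 17 of 19 members below a ratio of 1 but 1 lower by size, and Col3a1, a fibrillar collagen, was at 791 against 1125 CPM (0.703, 0.686 to 0.721). Myofibroblast and TGF-beta targets were at −0.20 (1 of 24 lower, 1 higher), although their member Spp1, a secreted phosphoprotein, was at 2.27 (1.84 to 2.80), and matrix crosslinking and proteolysis at −0.14 (5 of 30 lower), with the metalloproteinase inhibitor Timp1 at 0.487 (0.450 to 0.527). Elastic fibre and matrix glycoproteins were at −0.11, although Mfap4 belongs to that list, and lay within the central 95% of random lists matched on transcript length as well (−0.15 to 0.086). In Pi16 fibroblasts the medians were −0.025 for collagens, 0.056 for myofibroblast and TGF-beta targets, −0.019 for matrix crosslinking and proteolysis and 0.0015 for elastic fibre and matrix glycoproteins, all within the random range, against −0.25, −0.29, −0.25 and −0.18 in Asc1 fibroblasts.

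Lists above the random range were WNT, BMP and growth factor niche signals at 0.23 (5 of 29 higher by size, 2 lower), fatty acid oxidation and PPAR targets at 0.17 (3 of 26 higher, 1 lower), and nuclear-encoded oxidative phosphorylation at 0.15 (1 of 37 higher, 0 lower). Among the fibroblast classes, the fatty acid oxidation and oxidative phosphorylation medians lay above the random range in Asc1 (0.22 and 0.19) but within it in Gas6 (0.13 and 0.070), Pi16 (0.11 and 0.069) and myofibroblasts (0.12 and 0.090), and niche signals above it in all but myofibroblasts. Among niche signals, the WNT target Axin2 had a ratio of 1.79 (1.54 to 2.07), the hedgehog receptor Ptch1 1.64 (1.52 to 1.77) and the growth factor Hgf 1.57 (1.44 to 1.73), whereas the WNT modulator Sfrp1 was at 0.678 (0.610 to 0.753). In the fatty acid list, the dehydrogenase Acads was at 1.57 (1.32 to 1.87), whereas Pdk4, a kinase that restrains pyruvate oxidation, was at 0.347 (0.261 to 0.455). Cox6c, a subunit of cytochrome oxidase, was at 1.58 (1.53 to 1.63). Genes whose longest transcript had up to 800 nt had a median log2 ratio of 0.20.

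The medians of all remaining lists lay within the range of random lists matched on expression. They were 0.14 for the mitochondrially encoded respiratory chain, 0.13 for circadian clock output (just above the range when matched on transcript length as well, whose upper end was 0.129 against 0.130), 0.066 for lipid droplets and triglyceride turnover and 0.0029 for cholesterol efflux and LXR targets. They were −0.015 for hypoxia and glycolysis, −0.034 for the interferon response, −0.073 for fatty acid uptake and binding, −0.12 for proteoglycans and hyaluronan, −0.14 for the cell cycle and −0.16 for retinoid handling. Sex-linked transcripts were at 0.0079, with Y-linked Ddx3y at a ratio of 0.926 (0.878 to 0.977), Eif2s3y at 0.995 (0.898 to 1.10), Uty at 1.02 (0.860 to 1.20) and Kdm5d at 1.07 (0.834 to 1.37).

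**Figure D3:**
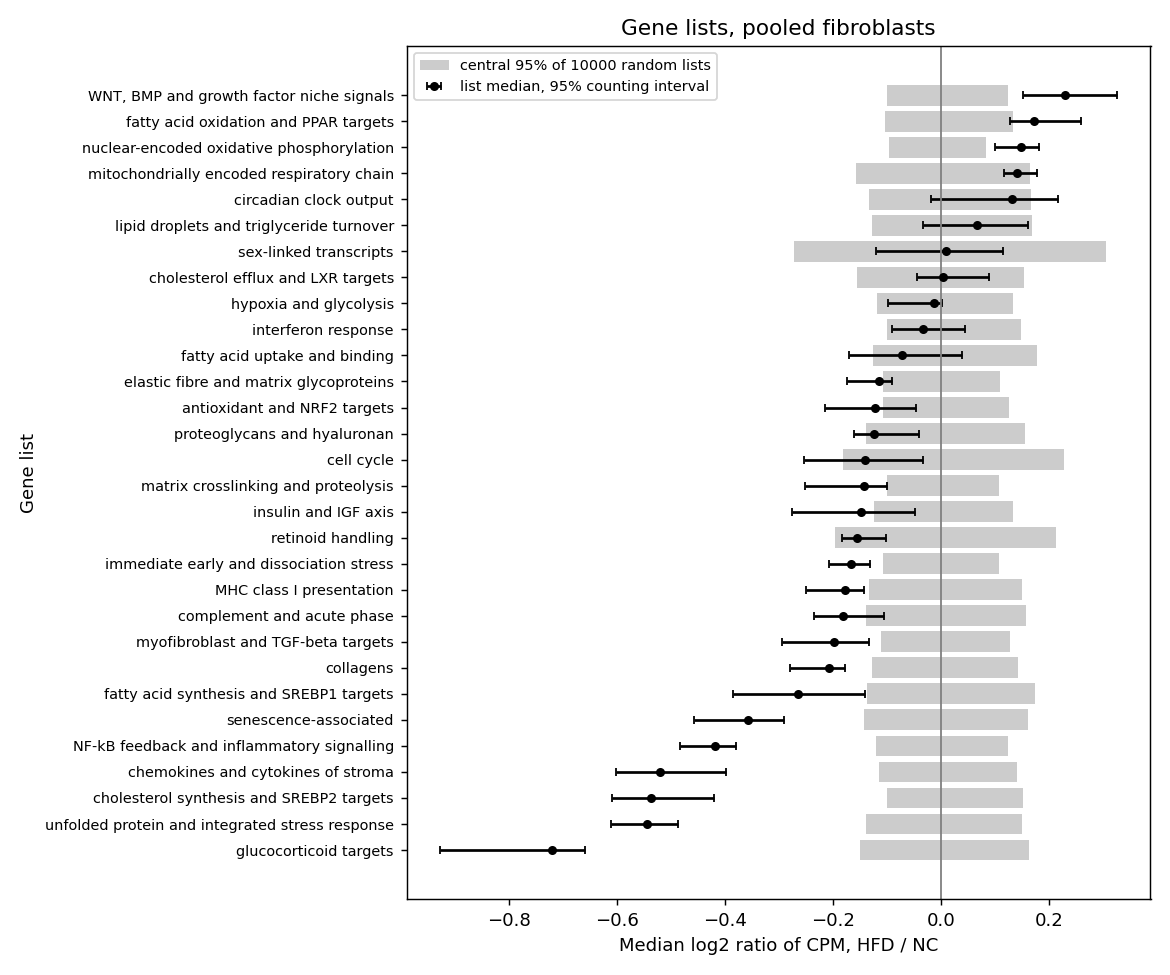
Median log2 ratio (HFD over NC) of each gene list in the pooled fibroblasts, with 95% counting intervals, over grey bars for the central 95% of 10000 expression-matched random lists. Glucocorticoid targets were lowest at −0.72, and WNT, BMP and growth factor niche signals highest at 0.23.

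The third comparison asked which genes ranked highest and lowest within single classes by the rule for named genes. In Asc1 fibroblasts, Mfap4 (ratio 2.39, 2.33 to 2.45), Mir682, Cox8b, Ifi27l2a and Hes1 were highest in HFD, and Zbtb16 (0.179, 0.141 to 0.224), Tsc22d3, Errfi1, Sgk1 and Igf1 lowest. In Gas6 fibroblasts, Mir682, Gucy1a1 (2.78, 2.23 to 3.47), Smim4, Mfap4 and Fabp3 were highest and Zbtb16, Manf, Hspa5 (0.377, 0.360 to 0.394), Has1 and Rhbdd2 lowest. In Pi16 fibroblasts, Mir682, Slc16a9, Aqp1 (2.08, 1.81 to 2.39), Cbfa2t3 and Wnt5a were highest and Cxcl2 (0.175, 0.111 to 0.267), Hspa5, Hsp25-ps1, Has1 and Hspb1 lowest. In myofibroblasts, Tcap (2.65, 2.15 to 3.28), Mir682, Efnb2, Dbp and Dpm3 were highest and Ccl7 (0.258, 0.172 to 0.377), Errfi1, Mir6236, Ccl2 and Igf1 lowest.

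In the class labelled pericytes, the sarcomeric gene Tcap was at 738 against 186 CPM (3.96, 3.43 to 4.59), and Mir682, Rgs5 and Sost were also among the highest. The heat shock gene Hsph1 was at 38.6 against 282 CPM (0.137, 0.109 to 0.171) and Hsp25-ps1 at a ratio of 0.199 (0.174 to 0.227). Some of these values rested on few of the 250 NC cells. The 10 cells with the most counts held 41.2% of NC counts for Tcap, 41.8% for Sost, 56.1% for Rgs5 and 83.9% for Timp1, which had a ratio of 0.184. Cytl1, at 41.5 against 761 CPM, had a count in 1 HFD and 4 NC cells, and Wif1, at 15.1 against 134 CPM, in 21 and 11, so the ratios of both describe a few cells.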

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

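The tests of class shares, dissociation stress, ribosomal protein genes and the cell filter, the test of doublets with fibroblasts, the test of diet against other differences, and length definitions other than the longest transcript were chosen after the results had been seen. Removal of the top doublet scores was chosen after the shares, but before its own value, had been seen.

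Earlier and later columns for the total count of a cell were compared, since the earlier ones entered no comparison. They were equal within 1% in 6.24% of HFD cells, against 100% of NC cells. Spearman correlations of earlier with later columns across HFD cells were 0.0494 for totals, 0.0634 for mitochondrial shares and 0.0467 for numbers of genes, and 1, 1 and 0.9998 across NC cells. The earlier HFD columns therefore do not describe most cells of their rows, and the cause was not tested. The class column does go with the expression values in HFD as in NC. Acta2 was at 12769 and 12126 CPM in the class labelled pericytes of HFD and NC and at 138 and 179 in the pooled fibroblasts, and Pi16 at 717 and 625 in Pi16 and 10.99 and 8.62 in Asc1 fibroblasts.

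Igkc, an immunoglobulin gene, also entered no comparison, and a single NC cell held 98.1% of its counts in that library (14879 of 15162).

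Glucocorticoid, unfolded protein and cholesterol synthesis genes were lower in HFD fibroblasts. After thinning cells to 2000 counts, the glucocorticoid median log2 ratio was −0.80. Thinning keeps the expected proportions of each cell, so this value does not decide on depth. With classes weighted equally the median was −0.65, which argues against class shares as the whole cause. The immediate early list lay 0.55 above the main glucocorticoid median, against an SD of 0.30 among its own members. This gap shows only that the lists were not equally low. Handling need not move both lists by the same amount, so the gap does not decide on it. Handling stays open, since the immediate early list was itself low. Heat shock genes were also among the lowest in the class labelled pericytes, where the median of that list was −0.35 (12 of 29 lower by size, 0 higher). Cells of mostly the Asc1 class were also spread differently over the clusters found here. At resolution 0.8, a cluster led by G0s2, Inmt and Npnt held 1432 HFD and 1125 NC cells. Hspb1 and Dusp1 were also among its leading genes. A cluster led by Ifrd1, Gadd45b and Thbs1, with Atf3 further down, held 731 and 1679. A cluster of mostly the Gas6 class, with Mt1, Mt2, Thbs1 and Il6 among its leading genes, held 317 and 970. At resolution 1.5, a cluster of mostly the Asc1 class held 492 HFD and 1081 NC cells. Its leading genes included the immediate early and stress genes Jun, Fos, Fosb, Atf3, Hspb1 and Dusp1. Whether the smaller Gas6 share and lower Mt2 in HFD are linked was not tested. Diet, animal, time of day and handling cannot be told apart with 1 library per group.

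The median log2 ratios of the oxidative phosphorylation list and of short transcripts were above 0 in the pooled fibroblasts. Of the 37 oxidative phosphorylation genes, 1 was higher by size. Among the fibroblast classes, that list lay above the random range in Asc1 only. On the longest transcript, which defined short ones, the oxidative phosphorylation genes had a median length of 1232 nt, above the limit of 800 nt. Without ribosomal protein genes, short transcripts had a median log2 ratio of 0.20, which argues against those genes alone. With them, the gap to longer ones was 0.24 after thinning and 0.22 before. Thinning keeps the expected proportions of each cell here too, so these values do not decide on depth. Among random lists matched on length, the oxidative phosphorylation median lay at percentile 99.5 with the longest transcript, 98.1 with the median one, 98.9 with the longest principal and 97.96 with the shortest principal one. Its counting interval (0.10 to 0.18) reached below the upper end of the matched range under each of these definitions (0.11 to 0.14), so a length trend and a difference of this list cannot be told apart.

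The class labelled pericytes held a larger share of HFD cells. The HFD over NC ratio of shares was 2.97 over all deposited cells, which argues against the cell filter used here as its cause. With the stricter filter the ratio was 2.89, and the difference was 2.85 percentage points, against 6.72 in the main setting. Cells left out before deposit could not be examined. Doublets with fibroblasts would raise fibroblast transcripts in this class. Over 26 fibroblast markers, the median level in the class was 14.9% of that in the pooled fibroblasts in HFD and 18.4% in NC. The median log2 difference of −0.23 (SD over markers 0.31) lay below the 0.58 set as the least rise, which argues against such doublets as the cause. The ratio of shares was 3.15 without the top doublet scores, but the caller marked no cell, so this value decides nothing on doublets of other kinds, which stay open. The yield of these cells on dissociation and a difference between animals or diets were not tested and stay open.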

How the results depend on the processing

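Own clusters at resolution 0.8 had been foreseen as the main classes, and only their use as an alternative was not planned. Removal of the top doublet scores, all deposited cells, leaving out the SNAT2 subset and counting near-tied clusters under their next name were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Keeping doublet calls moved nothing, since none were made. Over the scalings, the median log2 ratio of all genes shifted by −0.025 to 0.019. For named genes, 454 values under alternatives stayed within the counting interval, 49 left it in the same direction and 1 reversed, Aqp1 at −0.47 with classes weighted equally. For list medians, 641 stayed within it, 48 left it without a reversal of a list outside the random range, and 1 such list left it and reversed, the insulin and IGF axis at 0.020 without the Asc1 class. Of the lists within the random range, proteoglycans and hyaluronan, at 0.0045 with classes weighted equally, and hypoxia and glycolysis, at 0.0046 with totals without mitochondrial and ribosomal genes, left it and changed sign too, and other changes of sign stayed within it. Lists below the random range numbered 12 to 16 and those above it 2 to 4. The rule shared 11 named genes without a minimum CPM and 15 without the Asc1 class. Without that class the glucocorticoid median was −0.54 and the unfolded protein median −0.63, which was −0.43 without Gas6. The cholesterol synthesis median was −0.61 without Pi16. With equal weights it was −0.39, and the glucocorticoid median −0.65. With the stricter cell filter, the share difference (HFD minus NC, percentage points) was 5.52 for Asc1, −8.41 for Gas6, 1.57 for myofibroblasts, 2.85 for the class labelled pericytes and −2.89 for Asc1 and Gas6 together. In own clusters at resolutions 0.8, 0.4 and 1.5 and centred per library, the adventitial share, set against Pi16, differed by −10.2, −3.25, −3.36 and −3.70. The alveolar share, set against Asc1 and Gas6, differed by 3.83, a reversal, and by −3.10, −2.30 and −2.56. The reversal is set by the name of a cluster whose alveolar and adventitial scores differed by less than 0.1. With such near ties under the next name, the alveolar share differed by −2.88 at resolution 0.8, by 3.60, a reversal, at 1.5 and by −2.56 when centred, and the adventitial share by −3.47, −9.26 and −2.02. Fibroblast clusters were named by scores alone, and the leading genes of some held no marker of their name, so these shares are uncertain. For the other changes the cause was not tested. Depth limits genes near the count minimums, and no setting replaces a replicate.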

Other observations

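The values below were chosen after the data had been seen, and no explanation was tested for them. The SNAT2 subset made up 11.6% of deposited HFD and 10.97% of deposited NC cells, of which 30.2% and 36.3% passed the cell filter. Its deposited cells had median depths of 2730 and 2346 counts and median mitochondrial shares of 11.7% and 10.2%. Malat1, a nuclear transcript, was at 85672 and 81130.4 CPM in these cells, against 50098 and 45392 CPM in the rest of the Asc1 class. Slc38a2, which encodes the amino acid transporter SNAT2, was at 559 and 581 CPM in the kept cells of the subset and at 396 and 405 CPM in the whole Asc1 class.

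A cluster of 65 cells found here, 31 from HFD and 34 from NC, was pericyte-like and led by Gucy1a1, Postn, Cox4i2 and Pdgfrb. The deposited annotation placed 58.5% of it in myofibroblasts, and placed 96.9% of the smooth muscle-like cluster in the class labelled pericytes. A cluster of 139 cells led by histone genes, 38 from HFD and 101 from NC, stayed unnamed, as did 16 cells led by Cytl1, Chad, Wif1 and Snorc.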
